A study of Mus musculus with 9 samples.

How the data were processed

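Total RNA from 5 mouse tumours and 4 samples of normal skeletal muscle was measured on Affymetrix expression arrays, 1 array per sample. The tumours came from mice that the labels call MYF-5 CRE/SSM2. Per the labels' protocols, the tissue was disrupted by hand, RNA was extracted with Trizol and purified on RNeasy columns, and biotin-labelled target was made with a one-cycle kit.

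Per the submitters' processing notes, the authors made the values with MAS5, with no version, scaling target or background step given. The deposited values are probe set signals in units of intensity on a linear scale, and no detection calls were held in the table. The table held covered 30508 probe sets on 9 arrays, and other probe sets were not analysed here. Over the probe sets held, the 2% trimmed mean of an array ran from 429.7 to 609.7, a 1.42-fold range, while the array medians ran from 157 to 178. By a rule set beforehand, arrays whose trimmed means differed by more than 10% were scaled to a common 2% trimmed mean, with factors from 0.909 to 1.29. The number of arrays limits the precision, and intensities near an array's floor carry little signal over background.

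The 7 control probe sets were left out of the gene tests, as were 496 probe sets with several gene symbols and 4424 with none in the annotation. The remaining 25581 probe sets covered 14440 genes, and each gene was represented by its probe set with the highest mean level over all arrays. Of the single-symbol probe sets, 25498 matched a RefSeq gene, and 0 symbols needed an update. Probe positions in the genome were not used here. The floor of an array was the 40th percentile of its values, and a gene was tested if it reached the floor on at least 4 arrays, which left 10650 genes.

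Levels were log2(scaled value + 16). Tumour and muscle were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05, and called at least 2-fold changed if its log2 fold change was also at least 1 in size. Values per gene are given as the mean scaled intensity ± SD over the arrays of a group, and a log2 fold change is the difference of the mean log2 levels. A gene below the floor on every array of a group was given a bound, the mean of the other group against the floor, written as "at least".

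Before the data were examined, 33 gene lists were fixed, among them lists for cell types that a tumour or muscle sample could hold. The 31 lists with at least 5 tested members were tested with limma's camera at the preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Beside it stand camera with an estimated correlation and fry, which tests a list against no change where camera tests it against the other genes. An exact permutation test of list scores over all 126 splits of the arrays was added after camera with an estimated correlation had called 0 lists. For that test, a list score was the mean log2 level of the members on an array minus the mean of all genes. The list scores given below for single arrays are instead the mean over the members of the log2 level minus the muscle mean. For each list, the calls were also counted after adjustment over the list alone.

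The rule for named genes was also fixed beforehand. It took the 12 called genes with the largest change in each direction whose groups did not overlap, and up to 4 called members of each list with the largest change. It always took Ss18, Myf5, Myod1, Myog, Tle1, Bcl2, Pdgfra, Igf2, Ccnd1, Mki67, Cdh1, Krt8, Krt18, Ezh2, Pecam1 and Ptprc. It also took the 8 genes with the largest SD among tumours, and the control probe sets for the 3-prime to 5-prime ratios of Gapdh and Actb. This gave 147 genes, and 0 of them had another probe set called in the opposite direction. Other list members are named only as parts of their list, and genes named beyond the rule are identified as chosen after their values were seen. Igf2, Ptprc and the Gapdh control probe sets were not in the table held and were not analysed here.

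The alternatives planned beforehand were 4 other scalings, pseudocounts of 1 and 64, 2 other filters on dim genes, 2 other choices of probe set, counting probe sets, 3 other settings of the fit, and 2 treatments of the CC17 pair of tumours. They also included leaving out each array in turn, camera with an estimated correlation, and fry. Chosen after seeing the data were the values as deposited, leaving out tumours 1 and 4, leaving out muscles 2 and 3, the 3-prime to 5-prime ratio of Actb as a covariate, and the exact permutation of list scores. The closing section gives their effect.

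The procedure was tested on simulated data with known changes in 200 of 10650 genes and in the other members of the proteasome list. It recovered 23% of the genes changed 2-fold and 69% of those changed 4-fold, 2.91% of its calls were false, and 0 calls had the wrong direction. In the data 5113 genes were called, far more than were changed here, so the adjustment was stricter in the simulation. These recovery rates therefore do not carry over to the data. Camera called the changed list with either correlation, and called 0 of the other 30 lists. The noise was drawn for each gene by itself. The simulation therefore does not test lists whose genes vary together, such as the sarcomere list, with an estimated correlation of 0.802. Figures were drawn with matplotlib 3.10.9.

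The transgene that carries the human fusion of SYT and SSX was not analysed here. Whether the mouse Ss18 probe set also picks up its transcript was not tested, so that probe set is not read as a measure of the transgene.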

Results

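The data were 9 arrays of mouse tissue, 5 of tumours and 4 of normal skeletal muscle, with the values given as scaled intensity. Tumours 1 to 5 were labelled CC23, CC17-B, CC17-A, SSM5 and SSM4. Skeletal muscles 1 to 4 were hind limb, intercostal, forelimb and a further hind limb sample, all titled wild type. Genotype therefore differs together with tissue in every comparison. SYT-SSX is the fusion protein of synovial sarcoma, a soft tissue cancer, and Myf5, whose gene drives Cre in these mice, is a transcription factor of muscle precursors. The labels do not say whether each array came from a separate animal, so the p-values measure the spread between samples, and the number of arrays limits the precision.

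The comparison asked how the tumours of this mouse model differ from the normal tissue. Contractile and energy-producing transcripts of muscle were far lower in the tumours. Myh4, the fast myosin heavy chain, was at 1388 ± 2898 (SD, n = 5) in tumours and 63302 ± 13370 (SD, n = 4) in muscle. Tumour 5 carried the tumour mean, with Myh4 at 10.4% of the muscle level there, and without it the mean was 92.6 ± 120 (SD, n = 4). Of 47 cell cycle genes tested, 46 were higher in the tumours, as were the single genes Ptn, a secreted growth factor, and Sox2, a transcription factor. Ptn stood at 20391 ± 12136 (SD, n = 5) against 251 ± 105 (SD, n = 4), and Sox2 at 3235 ± 1553 (SD, n = 5) with every muscle array below the floor. Many tested genes of the Wnt, hedgehog and neural lists were higher in tumours. Of 18 endothelial genes 12 were lower, but 0 were with arrays centred on ribosomal protein and proteasome genes.

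Of 10650 genes tested with limma, 5113 (48.0%) were called, 3199 higher and 1914 lower in tumour, and 5859 had an unadjusted p under 0.05. Among the called genes, 2334 were at least 2-fold higher and 1409 at least 2-fold lower. The groups did not overlap for 4297 genes (40.3%), where chance gives 1.59%. Muscle was below the floor on all arrays for 304 of the higher genes, and tumour for 59 of the lower genes. The balance of higher and lower calls rested on the scaling. Higher calls made up 62.6% as reported, 44.2% with arrays centred on their median, and 88.0% with arrays centred on ribosomal protein and proteasome genes. The median log2 fold change of all genes was 0.23 as reported, −0.09 and 0.94 under those centrings, and list medians below can be read against it. No named gene changed sign under any of the 6 scalings. Relative to the median of all genes, over the 6 scalings, the median of the cell cycle list ran from 2.49 to 2.57, of the sarcomere list from −4.92 to −4.46 and of oxidative phosphorylation from −2.15 to −1.47. That of the endothelial list ran from −1.30 to −1.18 and that of the proteasome list from −0.87 to −0.34.

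**Figure D1:**
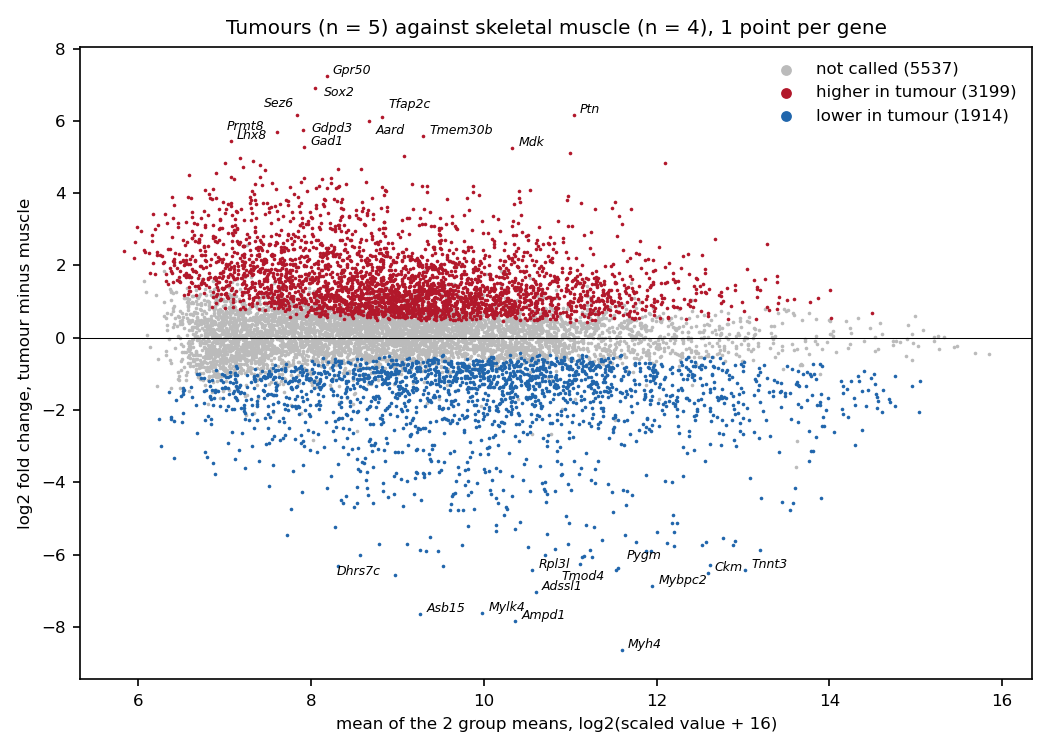
Log2 fold change of each tested gene (tumour minus muscle, vertical axis) against the mean of the group means of log2(scaled value + 16), 1 point per gene. The 3199 genes higher in tumour and 1914 lower are coloured, the 12 named genes with the largest change in each direction are labelled, and the fitted change of a gene below the floor in one group is no bound.

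Of the 12 largest increases, 9 were in genes below the floor on all muscle arrays. Gpr50 (1455498_at), a melatonin-related receptor, was at 3853 ± 1772 (SD, n = 5) in tumours, at least 30.2-fold higher than muscle. Sox2 (1416967_at), a transcription factor of stem and neural progenitor cells, was at least 24.6-fold higher (adjusted p = 2.5e-06). Tfap2c, a transcription factor, was at least 31.8-fold higher, but with only probe sets ending in _at another one represented it, with a log2 fold change of 3.40. Gad1, the enzyme that makes the transmitter GABA, was at least 12.7-fold higher. Ptn (1448254_at), the growth factor pleiotrophin, had a log2 fold change of 6.15 (SE 0.43, adjusted p = 4.8e-06). The rule that chose these genes required all 5 tumours to lie above all 4 muscle arrays. Sez6 was at least 16.3-fold higher, or 10.5-fold without tumour 2 and 27.6-fold without tumour 4 by the same probe set, but without tumour 2 another probe set represented it, with a log2 fold change of 1.33 (adjusted p = 0.0759), and without tumour 1 that value was 1.97 (adjusted p = 0.0360). Over its alternatives the adjusted p of Sez6 ran from 1.2e-05 to 0.0759.

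**Figure D2:**
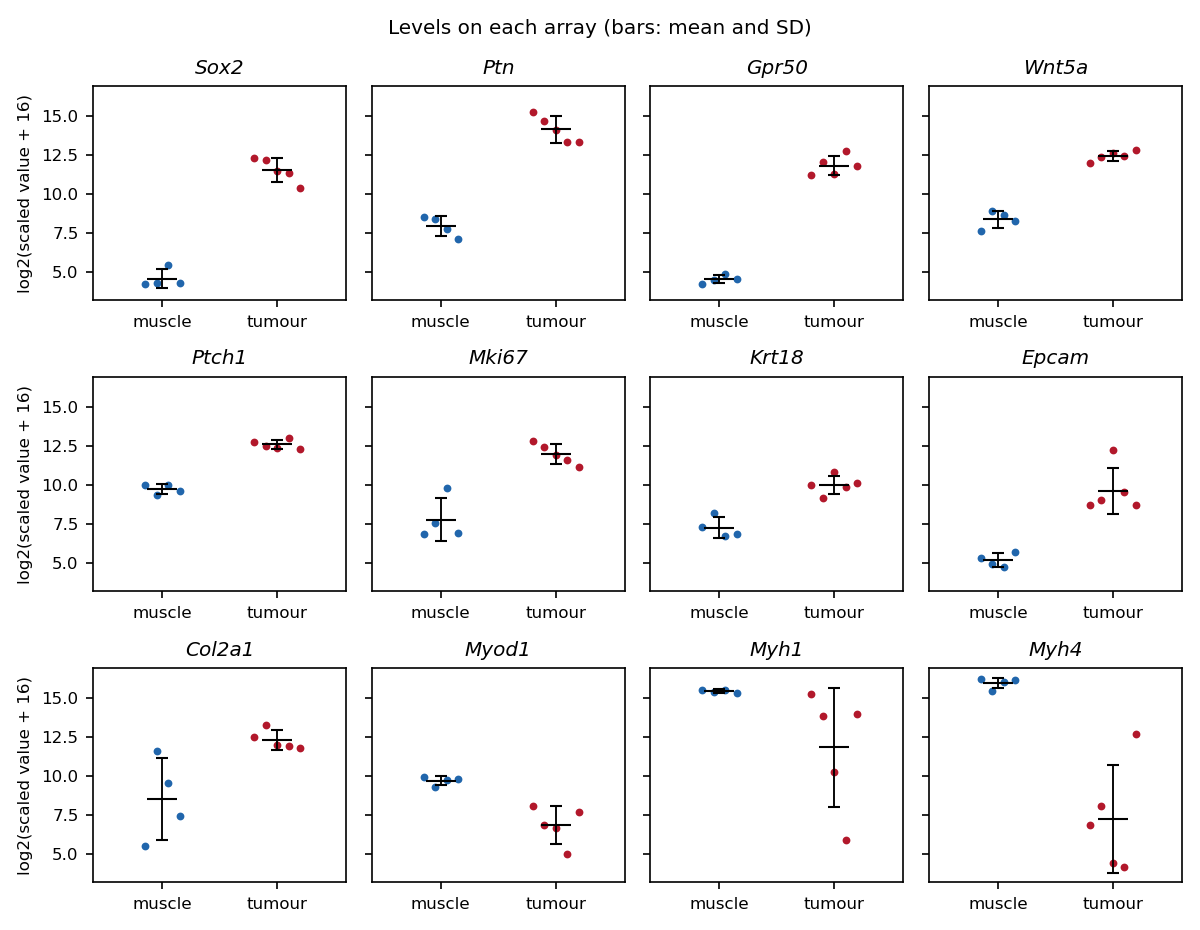
Levels of 12 genes on each array as log2(scaled value + 16), with blue points for the 4 muscle arrays, red points for the 5 tumours, and bars for the mean and SD. Sox2 and Gpr50 separate the groups, while Myh1 (adjusted p = 0.0745) overlaps them.

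Of the 47 cell cycle genes tested, 46 were higher, 0 were lower and 1 was not called, Gmnn, with a log2 fold change of 0.32. The count was also 46 when adjusted over the list alone. The median log2 fold change was 2.78, or 2.42 with the 7 genes below the floor in muscle at their bound. Mki67, the proliferation marker, was at 4336 ± 1913 (SD, n = 5) against 313 ± 375 (SD, n = 4), or 126 ± 39.8 (SD, n = 3) without muscle 3, with a log2 fold change of 4.19 (SE 0.56), or 4.86 without muscle 3. The D-type cyclins Ccnd2 and Ccnd1 rose by 4.83 and 3.07 on the log2 scale, and Bub1b, a spindle checkpoint kinase, was at least 5.30-fold higher. Camera called the list (adjusted p = 1.6e-13), with adjusted p = 0.167 with an estimated correlation.

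The list of synovial sarcoma markers had 24 of 33 members higher, 0 lower and 9 not called, and 26 higher when adjusted over the list alone. It was drawn from knowledge of the human disease, not from these samples. Its median log2 fold change was 1.51, and camera gave adjusted p = 1.1e-06, or adjusted p = 0.0848 with an estimated correlation. Beside Ptn, the strongest members were Mdk, the growth factor midkine, at 5.26, Tnfrsf19, a receptor of the TNF family, at 5.12, and Twist1, a mesenchymal transcription factor, which was 18.4-fold higher. Tle1, a transcriptional corepressor used to diagnose the human tumour, rose by 1.01 (adjusted p = 0.00117). Without tumour 1 another Tle1 probe set was taken, with a log2 fold change of 0.25 (adjusted p = 0.308), and without tumours 1 and 4 it was 0.27 (adjusted p = 0.354). Bcl2, which blocks apoptosis, rose by 0.88 (adjusted p = 0.00698), and its call ended when all its probe sets were averaged, at 0.17 (adjusted p = 0.595). It also ended with arrays centred on their median (adjusted p = 0.0507) and without muscles 2 and 3 (adjusted p = 0.0599). Pdgfra, a growth factor receptor of mesenchymal cells, rose by 1.02 (adjusted p = 0.0149), and its call ended without muscle 1 (adjusted p = 0.0522). Its call also ended on the values as deposited (adjusted p = 0.0819), with arrays centred on their median (adjusted p = 0.0799) and without muscles 2 and 3 (adjusted p = 0.0767). Over their alternatives the adjusted p ran from 0.00055 to 0.354 for Tle1, from 0.00487 to 0.595 for Bcl2 and from 0.00219 to 0.0819 for Pdgfra.

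Signalling genes of development were higher in part. In the Wnt list, 17 of 30 genes were higher, 3 lower and 10 not called (17 and 4 when adjusted over the list alone), with a median of 1.04. Wnt5a, a secreted ligand, was at 5647 ± 1205 (SD, n = 5) against 333 ± 122 (SD, n = 4). Lef1, a transcription factor of the pathway, rose by 3.82 on the log2 scale, Fzd1, a Wnt receptor, by 3.73, and Lgr5, a receptor of stem cells, by 3.56. Camera gave adjusted p = 0.0116, and adjusted p = 0.221 with an estimated correlation. In the hedgehog and Notch list, 15 of 21 genes were higher, 0 lower and 6 not called (15 when adjusted over the list alone), with a median of 1.46. Smo, the hedgehog signal transducer, rose by 3.29, and Ptch1 and Hhip, which bind hedgehog ligands, by 2.85 and 3.31. The camera test gave adjusted p = 0.00038, and adjusted p = 0.124 with an estimated correlation. In the FGF list, 8 of 17 genes were higher, 2 lower and 7 not called (9 and 2 when adjusted over the list alone), with a median of 1.26. Fgfr2, an FGF receptor, rose by 2.30 and Dusp6, a phosphatase of the ERK kinases, by 2.25, while the ligand Fgf1 fell by 2.32. Camera did not call the FGF list (adjusted p = 0.0633, and adjusted p = 0.281 with an estimated correlation). It did so without muscle 1 (adjusted p = 0.0483), muscle 4 (adjusted p = 0.0334) or tumour 4 (adjusted p = 0.0375), and under 9 other alternatives, while fry and the exact permutation test called it too. Over all settings of the fit and the samples, camera's adjusted p for the FGF list ran from 0.0199 to 0.0946.

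**Figure D3:**
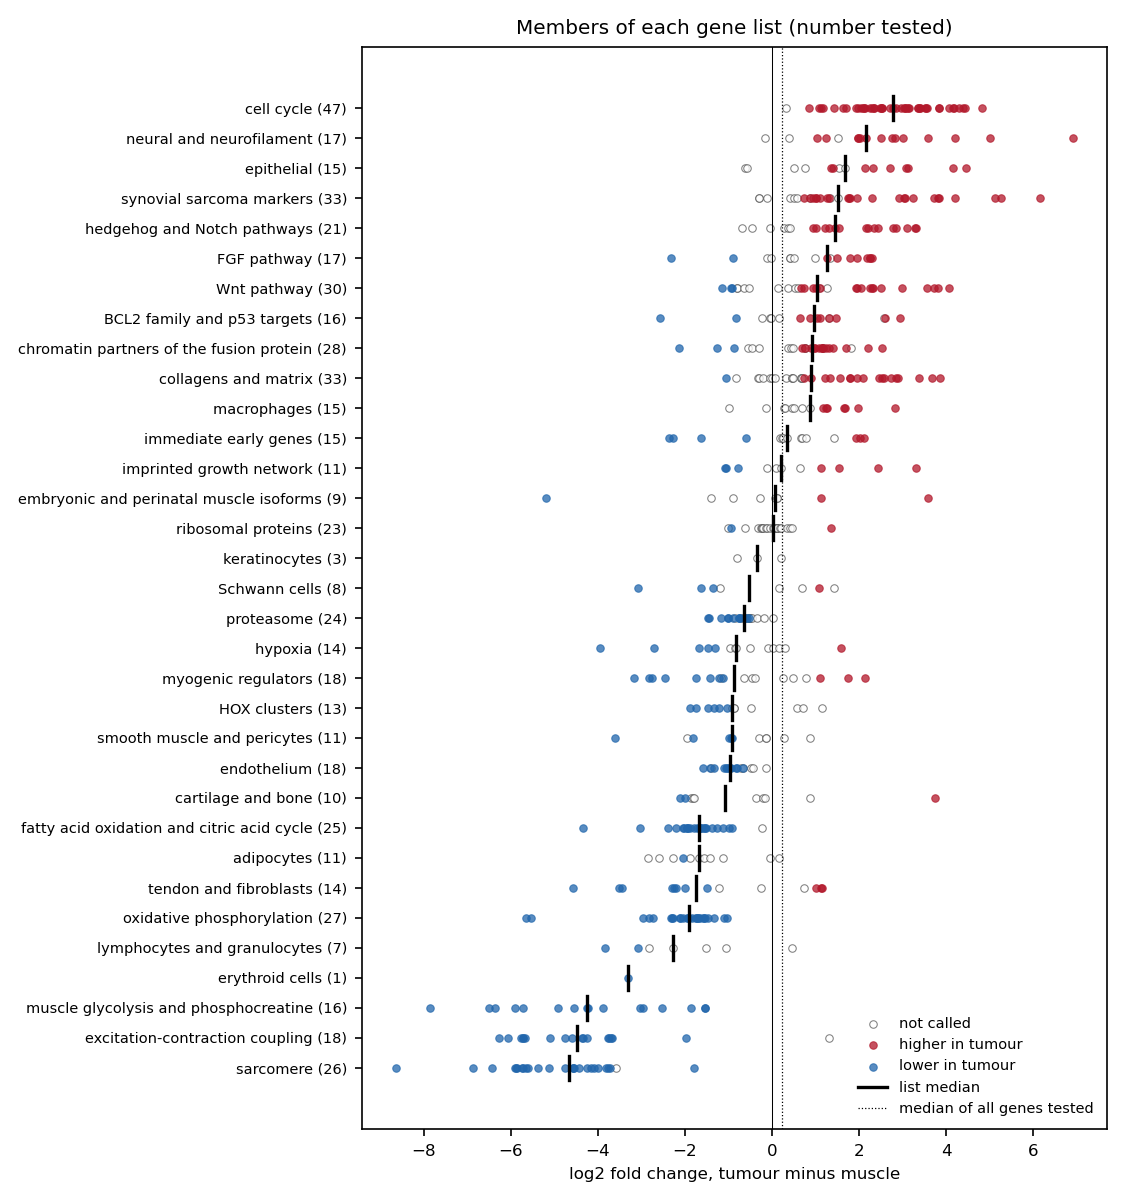
Log2 fold change (tumour minus muscle) of each tested member of the 33 gene lists, 1 point per gene, filled where called, with a black bar at the list median and a dotted line at the median of all genes (0.23). Cell cycle genes lie highest and the sarcomere and coupling lists lowest, and the medians of the embryonic isoform, keratinocyte, Schwann cell, imprinted, ribosomal protein and proteasome lists changed sign under at least 1 of the 5 other scalings, for the proteasome only under the centring on its own members and the ribosomal proteins.

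Of 27 neural and neurofilament genes in the table, 17 were tested. Of these, 14 were higher, 0 lower and 3 not called (15 higher when adjusted over the list alone), with a median of 2.16, or 1.98 with 4 genes at their bound. The neurofilament genes Nefl, Nefm and Nefh were not tested, and lay below the floor in all tumours, at 12.5 to 92.6. Chl1, a neural cell adhesion molecule, rose by 5.02 on the log2 scale, and Ngfr, the low-affinity neurotrophin receptor, by 4.21. By camera, the list had adjusted p = 2.1e-05, and adjusted p = 0.156 with an estimated correlation. Of 8 Schwann cell genes, 1 was higher, 3 lower and 4 not called (3 and 4 when adjusted over the list alone). Its median was −0.52, and relative to the median of all genes it ran from −0.80 to −0.74 over the 6 scalings. It was 0.19 with arrays centred on ribosomal protein and proteasome genes, which raises all genes. Camera did not call it (adjusted p = 0.469, and adjusted p = 0.642 with an estimated correlation).

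Among epithelial genes, 9 of 15 were higher, 0 lower and 6 not called, with the same count of 9 when adjusted over the list alone. Epcam, an epithelial adhesion molecule, was at least 6.70-fold higher, or at least 4.29-fold without tumour 3, and Dsp, a desmosome component, at least 9.49-fold higher. The simple keratins Krt18 and Krt8 rose by 2.71 and 2.14 on the log2 scale, and Cdh1, the adherens junction cadherin, by 2.32. The median was 1.67, or 1.54 with 3 genes at their bound, and camera gave adjusted p = 0.0116, or adjusted p = 0.408 with an estimated correlation. The list score of tumour 3 was 3.17, and those of the other tumours ran from 1.22 to 1.80. Of the 3 keratinocyte genes tested, 0 were called, also when adjusted over the list alone. Their median was −0.33, or 0.37 with arrays centred on ribosomal protein and proteasome genes, which raises all genes, and it ran from −0.68 to −0.56 relative to all genes over the 6 scalings. The list was too small for a list test.

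Of 33 collagen and matrix genes, 18 were higher, 1 lower and 14 not called, with the same counts when adjusted over the list alone. Vcan, a large proteoglycan, rose by 3.86, but its call ended when all its probe sets were averaged (0.78, adjusted p = 0.0512). Tnc, the matrix protein tenascin C, was at 4582 ± 1251 (SD, n = 5) against 413 ± 55.3 (SD, n = 4), and Fbn2, a microfibril protein, rose by 3.68. Dcn, a small proteoglycan of fibroblasts, was the member that fell, with a log2 fold change of −1.06. The median was 0.90, and camera gave adjusted p = 0.00136, or adjusted p = 0.311 with an estimated correlation. For Vcan the adjusted p ran from 2.4e-06 to 0.0512 over its alternatives.

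The contractile genes of muscle fell far. Of 26 sarcomere genes, 25 were lower, 0 higher and 1 not called (26 lower when adjusted over the list alone), with a median of −4.67. Myh4 (1427026_at) had a log2 fold change of −8.65 (SE 1.39, adjusted p = 0.00045), and Tnnt3, fast troponin T, one of −6.44. Without tumour 5 these were −10.00 and −7.29, and without tumour 4 they were −7.88 and −5.21. Myh4 lay below the floor in tumours 1, 3 and 4, so its fold changes are limited by background. Myh1, another fast myosin, was not called, with a log2 fold change of −3.58 (adjusted p = 0.0745). Without tumour 1 it was −4.43 (adjusted p = 0.0305), called there and under 3 other alternatives. Without tumour 4 another Myh1 probe set was taken, with a log2 fold change of −2.29 (adjusted p = 0.0653). Of 18 genes of excitation-contraction coupling, 17 were lower and 1 not called, with 17 lower also when adjusted over the list alone and a median of −4.48. Ryr1, the calcium release channel, had a log2 fold change of −6.08, and Pvalb, a calcium buffer, one of −6.28, or −6.75 and −7.09 without tumour 5, with Pvalb at −5.51 without tumour 3. The exception was Sln, a regulator of the calcium pump, with a log2 fold change of 1.31 (SE 1.84, adjusted p = 0.583). Over single arrays left out this ran from 0.53 without tumour 5 to 2.99 without tumour 4 (adjusted p = 0.0527), and was 2.63 without muscle 2, which carried the muscle mean of 3812 (368 without it). The adjusted p of Sln ran from 0.0527 to 0.831 over its alternatives. Camera gave adjusted p = 3.4e-11 for the sarcomere and 1.2e-10 for coupling. These were adjusted p = 0.264 and adjusted p = 0.201 with an estimated correlation. For Myh1 the adjusted p ran from 0.0164 to 0.225 over its alternatives.

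Energy metabolism of muscle fell with the contractile genes. All 16 genes of muscle glycolysis and phosphocreatine were lower, and all 16 when adjusted over the list alone, with a median of −4.24. Ckm, the muscle creatine kinase, had a log2 fold change of −6.50, and Pygm, the muscle glycogen phosphorylase, one of −6.36. Tumour 5 carried their tumour means, 3406 and 889, which were 1163 and 241 without it, and the log2 fold changes without it were −7.56 and −7.21. Without tumour 4 that of Ckm was −5.37. All 27 genes of oxidative phosphorylation were lower, also when adjusted over the list alone, with a median of −1.91. Within that list, the muscle isoforms Cox8b and Cox6a2 had log2 fold changes of −5.64 and −5.55 (−4.62 and −4.73 without tumour 4, and −6.33 for Cox8b without tumour 5), and Uqcrfs1, a subunit of complex III found in most tissues, one of −2.97. Of 25 genes of fatty acid oxidation and the citric acid cycle, 24 were lower, also when adjusted over the list alone, and Idh2, at −0.24, was not called. Their median was −1.68. The count of lower genes fell to 7, with a median of −0.97, with arrays centred on ribosomal protein and proteasome genes, where that of oxidative phosphorylation fell to 21, with a median of −1.21. Pdk4, a kinase that restrains pyruvate oxidation, had a log2 fold change of −4.35, and Ogdh, an enzyme of the citric acid cycle, one of −2.21. The camera test gave adjusted p = 8.5e-12, 4.7e-17 and 1.4e-11 for these lists in turn. They had adjusted p = 0.129, adjusted p = 0.0804 and adjusted p = 0.142 with an estimated correlation.

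Muscle transcripts did not stand at 1 level in the tumours. The score of the sarcomere list, in log2 units from the muscle mean, was −8.40 in tumour 4, −6.22 in tumour 3, −4.55 in tumour 2, −3.30 in tumour 1 and −2.31 in tumour 5. In tumour 4, 22 of the 26 genes were below the floor, and in tumour 3, 8 were, so these scores are limited by background. With such values set to the floor, the scores were −7.29 and −5.96, which are upper limits. Myh1 stood above Myh4 as a share of the muscle level in tumours 1 (89.5% and 0.162%), 2 (32.8% and 0.409%), 3 (2.73% and 0.00958%) and 5 (36.8% and 10.4%), with Myh4 below the floor in tumours 1 and 3. In tumour 4 both lay below the floor. Of the 73 named genes lower in tumour, 19 had a tumour mean over 1.5 times lower without tumour 5, and 20 had a fold change over 1.5 times larger. Myh1 and Tnni2, a fast troponin, were among the 8 genes with the largest SD among tumours.

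**Figure D4:**
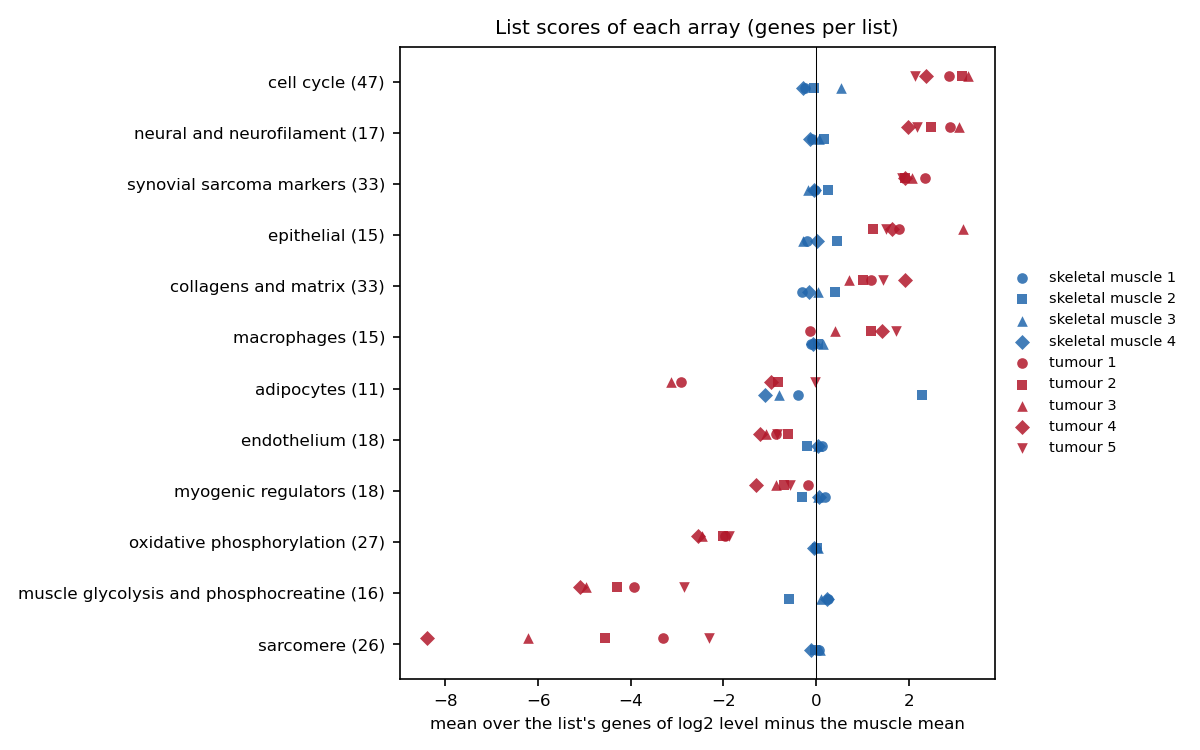
List score of each array, the mean over the members of the log2 level minus the muscle mean, for 12 lists, with muscle arrays in blue and tumours in red and a symbol per sample. Sarcomere scores of tumours run from −8.40, where 22 of 26 genes were below the floor, to −2.31, and skeletal muscle 2 stands apart at 2.29 for adipocyte genes.

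Transcription factors of the muscle lineage moved both ways. Of 18 myogenic regulators, 8 were lower, 3 higher and 7 not called (9 and 3 when adjusted over the list alone), with a median of −0.88. The count of lower genes was 4 with arrays centred on ribosomal protein and proteasome genes. Myf5 was at least 2.57-fold lower, with all tumours below the floor. Cre is driven by Myf5 in the tumour mice and the muscle is titled wild type, so genotype cannot be told apart from tissue here. Myod1, which commits cells to muscle, was at 130 ± 94.0 (SD, n = 5) against 821 ± 151 (SD, n = 4), a log2 fold change of −2.83. Myog, which drives differentiation, was not called, at −1.17 (adjusted p = 0.0525). It was called without tumour 3 (adjusted p = 0.0455), without tumour 5 (adjusted p = 0.00868) and under 7 other alternatives. The members that rose were Pax3 by 2.15, Eya1 by 1.75 and Pax7 by 1.11, all regulators of muscle precursors. Camera called the list lower (adjusted p = 0.0129), with adjusted p = 0.281 with an estimated correlation. The adjusted p of Myog ran from 0.00868 to 0.529 over its alternatives.

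Of 9 embryonic and perinatal muscle genes, 2 were higher, 1 lower and 6 not called, with the same counts when adjusted over the list alone. With arrays centred on their median, 1 was higher and 4 were lower. Ncam1, a neural and muscle adhesion molecule, rose by 3.58, and Actc1, the cardiac and fetal actin, fell by 5.19, with log2 fold changes of −6.17 without muscle 2 and −4.58 without tumour 4. Without muscle 4 another Ncam1 probe set was taken, with a log2 fold change of 2.94. The median was 0.06, negative under 4 of the 5 other scalings, while the mean was −0.30 and camera's direction was down. The list was not called (adjusted p = 0.584, and adjusted p = 0.632 with an estimated correlation).

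Of 28 chromatin partners of the fusion protein, 15 were higher, 3 lower and 10 not called (19 and 4 when adjusted over the list alone), with a median of 0.93. The counts were 8 higher and 6 lower with arrays centred on their median, and 20 and 1 with arrays centred on ribosomal protein and proteasome genes. Bcor, a Polycomb corepressor, rose by 2.52, and Ezh2, the histone methyltransferase of Polycomb, was at 2029 ± 992 (SD, n = 5) against 403 ± 119 (SD, n = 4). Smarcd3, a subunit of the BAF complex of heart and muscle, fell by 2.14. Ss18 (1419360_a_at), the mouse gene, rose by 1.17, and whether this probe set also picks up the fusion transgene was not tested. Camera called the list (adjusted p = 0.0378, and adjusted p = 0.281 with an estimated correlation). Its call ended without muscle 2 (adjusted p = 0.0926), without tumour 2 (adjusted p = 0.0502), without muscles 2 and 3 (adjusted p = 0.132), and under 4 other alternatives. Its adjusted p ran from 0.0117 to 0.132 over the alternatives with the preset correlation.

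Of 13 HOX genes, which set position along the body, 6 were lower, 0 higher and 7 not called, also when adjusted over the list alone, with a median of −0.91. The counts were 1 lower and 1 higher with arrays centred on ribosomal protein and proteasome genes, with a median of −0.20. Hoxd9 was at 169 ± 39.1 (SD, n = 5) against 712 ± 305 (SD, n = 4), and Hoxd8 fell by 1.74. The Hoxd8 call ended with arrays centred on ribosomal protein and proteasome genes (−1.03, adjusted p = 0.0963). By camera, the list had adjusted p = 0.0116, and adjusted p = 0.167 with an estimated correlation. The adjusted p of Hoxd8 ran from 0.00034 to 0.0963 over its alternatives.

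Of 18 endothelial genes, 12 were lower, 0 higher and 6 not called (13 lower when adjusted over the list alone), with a median of −0.95. The count was 0 of 18, with a median of −0.25, with arrays centred on ribosomal protein and proteasome genes. Tek, the angiopoietin receptor, fell by 1.42 on the log2 scale and Ramp2, a receptor partner for adrenomedullin, fell by 1.10. Both calls ended with that centring (adjusted p = 0.218 and adjusted p = 0.473). Pecam1 was not called, at −1.39 (adjusted p = 0.0581), and was called without tumour 1 (−0.85, adjusted p = 0.0313), without tumour 5 (adjusted p = 0.0217) and under 5 other alternatives. Of 11 genes of smooth muscle and pericytes, 5 were lower, 0 higher and 6 not called, also when adjusted over the list alone, with a median of −0.91, or 2 lower and a median of −0.21 with that centring. Abcc9, a subunit of potassium channels in pericytes and muscle, fell by 3.62, and Smtn, a smooth muscle cytoskeleton protein, fell by 1.81. Camera gave adjusted p = 3.9e-05 for endothelium and 0.0138 for smooth muscle, and adjusted p = 0.129 for both with an estimated correlation. Over their alternatives the adjusted p ran from 0.0004 to 0.218 for Tek, from 0.00084 to 0.473 for Ramp2 and from 0.0217 to 0.630 for Pecam1.

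Macrophage genes varied among the tumours. Of 15, 7 were higher, 0 lower and 8 not called, also when adjusted over the list alone, with a median of 0.87. Aif1, a macrophage calcium-binding protein, was at least 3.91-fold higher, and Mpeg1, a pore-forming protein of macrophages, rose by 1.97. List scores ran from −0.14 in tumour 1 to 1.73 in tumour 5. Camera did not call the list (adjusted p = 0.0855, and adjusted p = 0.632 with an estimated correlation), but did without tumour 1 (adjusted p = 0.0146), without tumour 3 (adjusted p = 0.0393) and under 3 other alternatives. Its adjusted p ran from 0.0108 to 0.314 over the alternatives with the preset correlation.

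Lower lists of other cell types moved with single muscle arrays. Of 7 genes of lymphocytes and granulocytes, 2 were lower and 5 not called (6 lower when adjusted over the list alone), with a median of −2.28. The count of lower genes was 5 on the values as deposited, and 1 of 5 tested without muscles 2 and 3. Skeletal muscle 3 had the highest score of that list, 2.27, and S100a8 there stood at 15781. Camera called the list (adjusted p = 0.0240, and adjusted p = 0.281 with an estimated correlation), and the call ended without muscle 2 (adjusted p = 0.0582), without tumour 2 (adjusted p = 0.0551) and without muscles 2 and 3 (adjusted p = 0.167). It also ended with arrays centred on their median (adjusted p = 0.0622) and with array weights (adjusted p = 0.0973). Without muscle 3 the camera call held (adjusted p = 0.0340), while the mean of the list relative to all genes moved from −2.21 to −1.47. Of 11 adipocyte genes, 1 was lower and 10 not called (0 lower when adjusted over the list alone), with a median of −1.68. On the values as deposited 3 were lower, and without muscles 2 and 3 it was 0 of 9 tested. Camera called this list (adjusted p = 0.0170, and adjusted p = 0.484 with an estimated correlation). Fry (adjusted p = 0.163) and the exact permutation test (adjusted p = 0.158) did not. Without muscle 2, where Adipoq stood at 40949, the camera call ended (adjusted p = 0.0778), as it did under 4 other alternatives. Of 10 cartilage and bone genes, 1 was higher, 2 lower and 7 not called, also when adjusted over the list alone. Col2a1, the cartilage collagen, rose by 3.75, by 2.74 without muscle 1, by 4.78 without muscle 2 and by 5.79 without muscles 2 and 3, and Sox6, a transcription factor, fell by 1.99. Their median was −1.08 and the list was not called (adjusted p = 0.0937, and adjusted p = 0.484 with an estimated correlation). It was called without muscle 1 (adjusted p = 0.0387), without muscle 4 (adjusted p = 0.0228) and under 2 other alternatives. Without muscle 2 its mean relative to all genes was −0.04, and without muscles 2 and 3 it was 0.39. With the preset correlation, adjusted p ran over the alternatives from 0.00101 to 0.167 for lymphocytes and granulocytes, from 0.00045 to 0.155 for adipocytes and from 0.0228 to 0.895 for cartilage and bone.

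Of 14 genes of tendon and fibroblasts, 8 were lower, 3 higher and 3 not called, also when adjusted over the list alone, with a median of −1.74. The counts were 5 lower and 3 higher with arrays centred on ribosomal protein and proteasome genes, and 8 and 0 with arrays centred on their median. Fmod, a proteoglycan of tendon, fell by 3.50 and Thbs4, a tendon and muscle matrix protein, fell by 2.30, while Scx, the transcription factor of tendon precursors, rose by 1.15. Camera called the list (adjusted p = 0.0119, and adjusted p = 0.167 with an estimated correlation), and its call ended without muscles 2 and 3 (adjusted p = 0.0633). Of the erythroid list, Alas2, the first enzyme of heme synthesis in red cells, was the single gene tested. It was lower, also when adjusted over the list alone, and at least 2.75-fold so. The adjusted p of the tendon list ran from 0.00029 to 0.0633 over the alternatives with the preset correlation.

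Stress and growth lists were mixed. Of 14 hypoxia genes, 5 were lower, 1 higher and 8 not called, also when adjusted over the list alone, with a median of −0.84. The count of lower genes was 3 with arrays centred on ribosomal protein and proteasome genes, with a median of −0.13, and 9 with arrays centred on their median. Among the members, Hk2, a hexokinase of muscle, fell by 3.95, and the member that rose was Kdm3a, a histone demethylase, by 1.59. The camera test gave adjusted p = 0.0116, and adjusted p = 0.129 with an estimated correlation. Of 16 genes of the BCL2 family and p53 targets, 8 were higher, 2 lower and 6 not called (10 and 2 when adjusted over the list alone), with a median of 0.96. Bcl2l11, which promotes apoptosis, rose by 2.59, or by 1.61 with the Actb ratio as a covariate, and Ccng1, a p53 target, fell by 2.58. Camera did not call the list (adjusted p = 0.255, and adjusted p = 0.317 with an estimated correlation), while the exact permutation test (adjusted p = 0.0129) did, as did fry (adjusted p = 0.00074), which tests against no change. Of 15 immediate early genes, 3 were higher, 4 lower and 8 not called (4 and 4 when adjusted over the list alone), with a median of 0.35. Fos, a transcription factor of the AP-1 complex, rose by 2.12, and Nr4a1, a nuclear receptor, fell by 2.36. That list was not called (adjusted p = 0.999, also with an estimated correlation). Of 11 imprinted growth genes, 4 were higher, 3 lower and 4 not called, also when adjusted over the list alone. Dlk1, a membrane protein of precursor cells, rose by 3.31, and Plagl1, a zinc finger regulator of the network, by 2.44. The median was 0.22, negative with arrays centred on their median, and the mean was 0.58, while camera's direction was down (adjusted p = 0.999, also with an estimated correlation).

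Of 23 ribosomal protein genes, 1 was higher, 1 lower and 21 not called, also when adjusted over the list alone. Their median was 0.02, negative in 2 of the 5 other scalings, while the mean was −0.03 and camera's direction was down (adjusted p = 0.469, and adjusted p = 0.888 with an estimated correlation). With quantile normalization and cyclic loess, 17 and 17 of the 23 were higher. Camera called them higher with quantile normalization (adjusted p = 3.3e-05) and cyclic loess (adjusted p = 0.0006), and lower with the Actb ratio as a covariate (adjusted p = 0.0373). Of 24 proteasome genes, 12 were lower, 0 higher and 12 not called, also when adjusted over the list alone. Psmd12, a subunit of the regulatory particle, fell by 1.44. The list median was −0.63, and 20 genes were lower with arrays centred on their median. With arrays centred on ribosomal protein and proteasome genes the list median was 0.08, 0 of 24 were lower and Psmd12 had adjusted p = 0.126, but the members are part of the reference there, so that centring does not test them. By camera, the list had adjusted p = 9.6e-06, and adjusted p = 0.167 with an estimated correlation. Over the alternatives the adjusted p ran from 3.3e-05 to 0.986 for the ribosomal protein list and from 2.2e-05 to 0.126 for Psmd12.

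Across the 31 lists tested, camera at the preset correlation called 8 higher and 14 lower. Camera with an estimated correlation called 0, with 9 lists at an unadjusted p under 0.05. Fry called 23 lists, and the exact permutation test called 23, of which 21 were also called by camera. Fry sets a list against no change, while camera and the permutation of list scores set it against the other genes, so the fry calls do not answer the same question. The size of some changes rested on the probe set taken: with all probe sets of a gene averaged, Chl1 rose by 2.74, Ngfr by 2.40, Tnfrsf19 by 3.14, Gad1 by 3.05, Lgr5 by 2.29, Ptch1 by 1.61, Ncam1 by 1.65, Plagl1 by 1.44, Tle1 by 0.57 and Bcl2l11 by 1.33, and Fgf1 fell by 1.38, all still called. An exact permutation p of 0.00794 is the smallest that the 126 splits can give.

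The tumours were less alike than the muscle samples. The median SD of a gene's log2 level was 0.463 among tumours and 0.307 among muscles, with a median ratio of 1.49, and 7442 of 10650 genes had the larger SD among tumours. The ratio was 2.20 without muscle 2 and 3.17 without muscles 2 and 3. Pearson correlations across genes, which are not independent replicates, ran from 0.787 to 0.910 between tumours, from 0.910 to 0.965 between muscles, and from 0.594 to 0.759 between a tumour and a muscle. The first principal component held 64.9% of the variance and separated tumours from muscle. The second held 12.6% and placed tumour 1 (61.9) at the other end from tumours 4 and 5 (−49.3 and −43.5), with tumours 2 and 3 between them. Its sign followed the tumour names, positive for those labelled CC and negative for those labelled SSM. The labels do not say what these names mean, so a batch or line cannot be told apart from other differences.

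The 3-prime to 5-prime ratio of Actb was highest in tumour 1. It was 12.7 in tumour 1, 4.54 in tumour 4, 2.90 in tumour 2 and near 2 in tumours 3 and 5, at 1.99 and 2.04. In the muscle arrays it ran from 1.62 to 1.93. The group means were 4.84 ± 4.54 (SD, n = 5) and 1.76 ± 0.137 (SD, n = 4), with a two-sided exact permutation p of 0.0556, adjusted to 0.222 over 4 array measures. The same ratio of Pcx, pyruvate carboxylase, was 2.99 in tumour 1, ran from 2.00 to 6.66 in the other tumours and from 3.44 to 6.34 in the muscle arrays. Its means were 3.95 ± 1.91 (SD, n = 5) and 5.29 ± 1.27 (SD, n = 4), with an exact permutation p of 0.230, adjusted to 0.328. The sarcomere scores of tumours 1 and 4, the arrays with the highest Actb ratios, lay at −3.30 and, with most genes below the floor, −8.40. Without these arrays 2689 genes were higher and 1789 lower, of 10025 tested. A gene still had to reach the floor on 4 arrays, and fewer than 4 tumours remained. Genes below the floor on all muscle arrays, such as Sox2, therefore had no result there.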

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

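The tests of muscle share, RNA degradation, array scaling among the tumours, marrow, cartilage and fat, and nervous tissue were chosen after the results they weigh had been seen. The tests of scaling of skeletal muscles 2 and 3 and of other splits of the arrays were not.

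A sample was singled out where its gap to the nearest other sample of its group took up more of the group's range than Dixon's 95% limit allows. Chance does this in about 1 in 20 groups, or 18.2 of the 364 examined, and 28 were found. Skeletal muscle 2 had 15 of them, and each other array at most 3. The gap, as a share of the range, is the value given for each.

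Skeletal muscle 2 was lowest for the excitation-contraction coupling score (0.857) and for the muscle genes Asb15 (0.843), Mylk4 (0.896), Dhrs7c (0.862), Rpl3l (0.830), Pvalb (0.925), Actc1 (0.941) and Abcc9 (0.853). It was highest for the Wnt score (0.833), the imprinted growth score (0.8498), and for Cd36 (0.936), Peg3 (0.837), Ccnd2 (0.905), S100b (0.928) and Plagl1 (0.940). Skeletal muscle 3 was highest for Ngp (0.836) and for Sox2 (0.956), where all muscle arrays were below the floor, and lowest for Ngfr (0.839).

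Among tumours, tumour 1 was highest for the 3-prime to 5-prime ratio of Actb (0.763) and lowest for Ogdh (0.752) and Kdm3a (0.758). Tumour 2 was lowest for the HOX score (0.715) and highest for Alas2 (0.784), below the floor in all tumours. Tumour 3 was highest for Epcam (0.760) and lowest for Car3 (0.747). Tumour 4 was lowest for Gad1 (0.787) and Chl1 (0.729) and highest for S100b (0.749).

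Muscle transcripts differed widely among the tumours, at a median of 14.9% of the muscle level in tumour 5 and, with values below the floor set to it, at most 0.565% in tumour 4. RNA degradation and array scaling are argued against as the whole cause, since tumour 5 lay 3.34 above tumour 3 on the log2 scale at the median muscle gene (95% bootstrap interval 2.94 to 3.99, or 3.27 with floored values) at Actb ratios of 2.04 and 1.99 and with the higher Pcx ratio (5.17 against 2.00), and the muscle levels ranged 10.4 times as widely as the scale factors (8.48 with floored values). Normal muscle in the excised tissue may account for the muscle transcripts of tumour 5, where the SD over 42 muscle genes of the log2 ratio to muscle, 1.18, was 0.935 times that of muscle 2, the most deviant muscle array, and 1.34 times that of muscle 4, the next, against a bound of 1.5. A share of muscle cannot be told apart from untested muscle differentiation in tumours 1 and 2, which met that bound against muscle 2 (1.403 and 1.22) but not muscle 4 (2.01 and 1.75), and in tumours 3 and 4 too few of these genes reached the floor (66.7% and 23.8%). In tumour 1 the level of Myh4, below the floor, allows at most 0.310% of muscle like that sampled, against a median gene at 7.24%, which counts against such muscle, but the other 41 genes allow 4.23% or more, and in tumour 2 Myh4 allows at most 0.585% and Ryr1 1.28%, against a median gene at 3.32%. In tumour 5 Ttn allows at most 6.75%, and the other 41 genes 11.3% or more, against a median gene at 14.9%.

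Skeletal muscle 2 stood apart from the hind limb arrays, with Pearson correlations across genes of 0.912 and 0.910 to them. Muscle 3, at 0.955 and 0.953, differed from them in some genes only. Over all tested genes muscle 3 differed from the other muscle arrays by a median of 0.0227 and muscle 2 by −0.0242 on the log2 scale. These values had already been scaled to a common trimmed mean, which favours a median near 0, so they cannot decide whether scaling was a cause. The scale factors of the muscle arrays ran from 0.915 to 1.04. Bone marrow in the tissue of muscle 3 is a candidate source, since 12 marrow genes outside the fixed lists were higher there by a median of 1.92 (95% bootstrap interval 1.06 to 2.93), among them Lcn2 at 2200, Prtn3 at 1051 and Elane at 589. Cartilage and brown fat may have been in the intercostal tissue of muscle 2, since 8 such genes outside the fixed lists were higher by a median of 2.34 (1.25 to 3.64), among them Thrsp at 23616, Snorc at 2198 and Ucma at 1234. Neither kind of transcript was confined to its array. Some marrow genes, such as S100a9 and Camp, were also higher on muscle 2 than on both hind limb arrays, while others, such as Igll1, were not. Some cartilage genes, such as Cnmd and Col9a3, were higher on muscle 3, while others, such as Ucma, were not. The anatomical site of the muscle, which the labels give, stays open as an untested biological source, since each site other than hind limb has 1 array.

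Many neural genes were higher in tumours. Without tumours 1 and 4, 13 of the 17 list genes were still tested, with a median of 2.04 (95% bootstrap interval 1.28 to 2.996). That argues against RNA degradation for these genes. Nervous tissue in the samples cannot be told apart from expression by the tumour cells, since 11 neuron and myelin genes outside all fixed lists, with low levels in muscle, went both ways. Their median log2 difference was 0.309 (95% bootstrap interval −0.313 to 1.69), with 6 of 11 higher, among them Prph, at least 10.8-fold, and Eno2, at least 4.77-fold. The design does not separate cell types.

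Other splits of the 9 arrays into groups of 5 and 4 were counted over 100 splits, the real one included. As many genes higher as the real 3199 came from 1 split, the real one, with 1201 the highest of the others. As many lower as 1914 came from 1 split, with 1677 the highest other. At least 2-fold higher, 2334 genes were matched by 1 split (highest other 1066), and at least 2-fold lower, 1409 genes were matched by 2 splits (highest other 1419). Such gene counts were rare among the splits counted, in at most 2 of 100, also when either direction is counted. Every other split mixed tumours with muscle, and 95 of the 100 called 0 genes. The 14 lists lower in tumour were reached by 4 splits, with 15 the highest other, but by 7 when either direction is counted, and 1 split with 0 genes called gave 7 lists higher and 15 lower. The 8 lists higher in tumour were reached by 35 splits, with 14 the highest other. Most of these splits had 1 or 2 tumours on the larger side, and so carried part of the tumour-muscle difference in reverse. They cannot decide whether chance gives as many lists, so chance is not excluded for the number of lists in either direction. The other splits that called any genes set all 4 muscles with 1 tumour: tumour 5 gave 1201 higher and 1677 lower, tumour 4 gave 529 and 801, tumour 2 gave 412 and 788, and tumour 3 gave 2 and 2. The split of this kind with tumour 1 was not among the 100 counted.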

How the results depend on the processing

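Chosen after seeing the data were the tests on values as deposited, without tumours 1 and 4, without muscles 2 and 3, with the Actb ratio as a covariate and by exact permutation of list scores. The rule that a list's direction is the sign of its mean shift was set after a first run, which had used camera's direction and gave more reversals. Over 27 settings, the 147 named genes gave 3733 results with the reported direction and call, 134 that lost the call, 20 that gained it and 0 reversed, with any change in 39 genes. The 31 lists gave 756, 18, 22 and 8 in turn, with any change in 10 lists.

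With arrays centred on ribosomal protein and proteasome genes, lower genes fell to 572 and to 544 at 2-fold, and genes at least 2-fold higher rose to 4142. That setting takes 1 median over lists that lie at different levels, and the cause was not tested. Counting 19661 probe sets in place of genes gave 4840 higher and 3101 lower, with 3743 and 2394 at 2-fold, since more features were tested. Camera with an estimated correlation called 0 lists higher and 0 lower, with 9 at an unadjusted p under 0.05, while fry called 10 and 13, and exact permutation 10 and 13.

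Reversed values, given as the mean of a list relative to all genes, were these. Ribosomal proteins moved to 0.558 with quantile normalization, 0.502 with cyclic loess and 0.125 with only probe sets ending in _at. Imprinted genes moved to −0.0740 with those probe sets. Immediate early genes moved to −0.0366 with the Actb covariate, and ran from −0.0187 to 0.161 over single arrays left out. Cartilage and bone moved to 0.387 without muscles 2 and 3, the arrays with cartilage and blood cell transcripts. The cause was not tested for the others.

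The ratio of SDs ran from 1.29 to 2.20 over single arrays left out, the highest without muscle 2, and was 3.17 without muscles 2 and 3. Leaving out single arrays gave 2716 to 3339 genes higher and 1499 to 1956 lower. The counts were 2442 and 1348 without muscles 2 and 3, 2863 and 1548 with the Actb covariate, and 2470 and 1989 on the values as deposited. With the CC17 tumours averaged, 3063 genes were higher and 1881 lower, and the ratio of SDs was 1.36. The CC17 tumours as 1 block were not run, since a correlation was estimated for 0 genes from a single pair, and lists were not run with the robust trend. A gene not tested under a setting, or a list left with fewer than 5 tested members, has no result there. Genes near the floor are limited by signal over background.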

Other observations

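No test is reported in this part, and the genes were chosen after their values were seen. Peripherin (Prph), an intermediate filament of peripheral neurons that is in none of the fixed lists, ran from 893 to 1668 in the 5 tumours and from 10.2 to 80.1 in the 4 muscles, at least 10.8-fold higher. Eno2, the neuronal enolase, was at 597 ± 266 (SD, n = 5) in tumours and 71.9 ± 3.29 (SD, n = 4) in muscle. Col2a1 stood between 3553 and 9869 in the tumours, while Acan, the main proteoglycan of cartilage, stood between 75.4 and 133 there. On skeletal muscle 2 the levels were 3124 for Col2a1 and 3411 for Acan.

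Tumours 4 and 5 were the most alike of the tumour pairs, with a Pearson correlation across genes of 0.910, and the CC17 pair had 0.901. Tumours 1 and 4 were the least alike, at 0.787. Transcripts of brown fat appeared in tumour 2, with Cidea at 874 and Ucp1 at 563.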
